A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

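Small-RNA libraries from liver tissue of wild-type rainbow trout were compared, 3 from control, 3 from moderate hypoxia and 3 from acute hypoxia for 12 h, per the labels. Total RNA had been extracted with Trizol and libraries made with standard Illumina protocols. The aligner, the genome build, the counting step and the tool that predicted miRNAs are not given in the sources used here.

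The deposited file stacks 3 tables, 1 for each pair of groups, each with its own header line. Its abundance values, a signal scaled to reads of the library, are named TPM per the file headers, and their sums per library and table were checked to lie close to one another. The deposited fold changes are on the log2 scale and equal the log2 of the ratio of the second group's mean to the first group's mean. The deposited p-values and false discovery rates come from a test of the authors that the file does not name. The tables of moderate hypoxia with control and of acute with moderate hypoxia hold the same 1413 entries with the same moderate hypoxia values, and were joined over all 9 libraries. The table of acute hypoxia with control holds 1139 entries of another naming run: of 347 predicted names that both share, 7 carry the same sequence, and of 399 known names 344 do. It was used for the predicted miRNA in the title of the series and as an alternative. Predicted miRNAs are given by their sequences in place of their names in the file. Of the 1413 entries, 263 repeat the sequence of an earlier one and were kept.

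Low values are whole multiples of 1 step per library, which returned the reads behind them: 8443329 to 16515713 per library, with 99.9 to 100% of the values within rounding of whole numbers. A count of 3 reads corresponds to 0.182 to 0.355 TPM. Reads without molecular identifiers are not independent molecules, so counting intervals (95%, exact) and floors of 3 reads cover counting error only.

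Values were analysed as log2(TPM + 1) for entries with a mean of at least 1 TPM over the 9 libraries (481). One limma-trend model (limma 3.58.1, R 4.3.3) with 3 group means was fitted to all 9 libraries, and the 3 comparisons were adjusted by Benjamini and Hochberg within each, at 0.05. Groups of 3 leave an exact permutation test a smallest two-sided p of 0.1, and such tests (scipy 1.17.1, Python 3.11.15) served the shares and that predicted miRNA. Lists of miRNAs, 25 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 3 members were tested (22 lists), and again with an estimated correlation. They cover hypoxia-responsive miRNAs of mammals, the teleost pair miR-462 and miR-731, liver-enriched miRNAs, glucose and lipid metabolism, let-7, miR-17-92, miR-30, miR-29, miR-181, miR-15/16, the group of miR-10, miR-99, miR-100 and miR-125, the cluster of miR-183, miR-96 and miR-182, miR-34, oxidative stress and inflammation, teleost-specific miRNAs and predicted miRNAs. Lists of other cell types and tissues cover red blood cells, leukocytes, endothelium, stroma and smooth muscle, epithelium, striated muscle, nervous tissue, gonad and embryo, and pancreas. Members were matched on the miRNA number, so a list takes every arm and copy.

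The miRNAs named were set by a rule fixed before the data were examined. Per comparison it takes, among those past the threshold with a mean of at least 10 TPM and groups that do not overlap, up to 12 with the largest rise and up to 12 with the largest fall; with fewer than 10 past it, the 10 smallest unadjusted p-values. It adds the predicted miRNA in the title of the series, every miR-210, miR-462, miR-731 and miR-122, the 10 most abundant miRNAs, and of each list 4 examples and the members past the threshold. Because members past the threshold were many, at most 4 of them per list and comparison are printed, those with the highest mean, a limit set after the values were seen. Some of the list examples and of the 10 smallest unadjusted p-values are not printed. The names that stand for entries high in single libraries were also chosen after their values were seen, as were the counts of calls that library 3 shares.

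The correlation of the 2 changes against control was set beside 100 simulated draws of unchanged groups with shared controls. The method was tested on simulated data with 200 changed miRNAs: 2-fold changes were found in 67.2% (moderate hypoxia against control), 80.6% (acute hypoxia against control) and 71.6% (acute against moderate hypoxia) of cases, 4-fold changes in 100%, 95.5% and 98.5%, and 1.5-fold changes in 31.3%, 37.3% and 31.3%. Of all calls there 5.71%, 3.40% and 3.60% were false. Every simulated miRNA had the same dispersion (0.0518), and with fewer changed miRNAs the shares found would be lower.

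Other settings fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 TPM, scaling by a trimmed mean of M values (30% and 5% trims, computed here), by the median of ratios (computed here) and by quantiles, leaving out the most abundant miRNA, the replicate number as a block, only the 6 libraries of a comparison, no mean-variance trend, other thresholds, and each library left out in turn. Pooling entries of 1 name changed nothing, since names are already unique. Added after the data were seen were 1 entry per distinct set of values over the libraries, which leaves some repeated sequences in, and voom on recovered reads. Also added were the table of acute hypoxia with control alone and removing a trend on GC content and length. The last were leaving out moderate hypoxia libraries 1 and 2 together and leaving out the 58 entries high in those libraries. The replicate numbers are not said to pair libraries, and correlations between libraries of the same number (-0.206 to 0.264) gave no pairing. Tables were handled with pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9.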

Results

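Small RNA from the liver of wild-type rainbow trout was sequenced in 9 libraries, 3 from control fish and 3 each from fish under moderate and under acute hypoxia for 12 h. The deposited values are scaled read abundances (TPM) of 1413 miRNA entries, of which 540 carry the name of a known miRNA and 873 were predicted from the reads. Predicted miRNAs are given here by their sequences in place of their names. The reads behind them numbered 10346821, 10264506 and 9075436 in the control libraries, 11125144, 14878879 and 16515713 under moderate hypoxia, and 11841128, 8443329 and 8784153 under acute hypoxia. Of the entries, 481 reached a mean of 1 TPM and were tested, and these hold 399 distinct sequences. The labels do not say whether the 3 libraries of a group come from separate fish, so p-values measure only the spread between these libraries. The letters x, y and z that end the known names are printed as the file gives them, without a stated meaning. Genome positions of the miRNAs are not given in the sources used here. The mRNA, the lncRNA, the histology, the biochemistry and the reoxygenated fish of the study are not analysed here.

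The liver miRNA pool was dominated by miR-122-x, the hepatocyte miRNA, at 422328 ± 101660 TPM in control, 516116 ± 10428 TPM under moderate hypoxia and 434164 ± 27565 TPM under acute hypoxia (SD, n = 3). Next in mean abundance came miR-199-x, miR-100-x, miR-30-x, miR-22-y, let-7-x, miR-192-x, miR-26-x, miR-181-x and miR-101-y. The first principal component held 58.1% of the variance of the tested miRNAs and held the 3 moderate hypoxia libraries at 15.3, 17.1 and 7.83 and the other 6 between -9.03 and -3.23, so library 3 lay nearer the other groups than libraries 1 and 2 did. Over the tested miRNAs library 3 had a correlation of 0.980 and 0.975 with libraries 1 and 2, and of 0.965, 0.976 and 0.978 with the controls.

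Moderate hypoxia libraries 1 and 2 also held reads under names that stand apart from the rest. The 35 entries named for the imprinted miRNA cluster of placental mammals, miR-127 and miR-434 among them, summed to 246 and 300 TPM in those libraries and to 3.94 TPM in moderate hypoxia library 3. In the control libraries these entries summed to 3.96, 3.02 and 4.52 TPM, and in the acute hypoxia libraries to 5.32, 4.03 and 3.76 TPM. In all, 58 entries were more than 4 times higher in both of these libraries than in any other, 21 of them were tested, and 16 passed the test of moderate hypoxia against control. Library 3 lay above every control for 15 of the 58. Library 3 of this group lay between libraries 1 and 2 at 87.2% of the 94 miRNAs with at least 100 TPM. The next highest share of any library was 66.0%, in acute hypoxia library 3. If moderate hypoxia library 3 is not independent of libraries 1 and 2, the p-values of the moderate hypoxia comparisons are too low. The groups share 1 estimate of spread, so those of acute hypoxia against control, the list tests included, may then be too low as well.

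**Figure D1:**
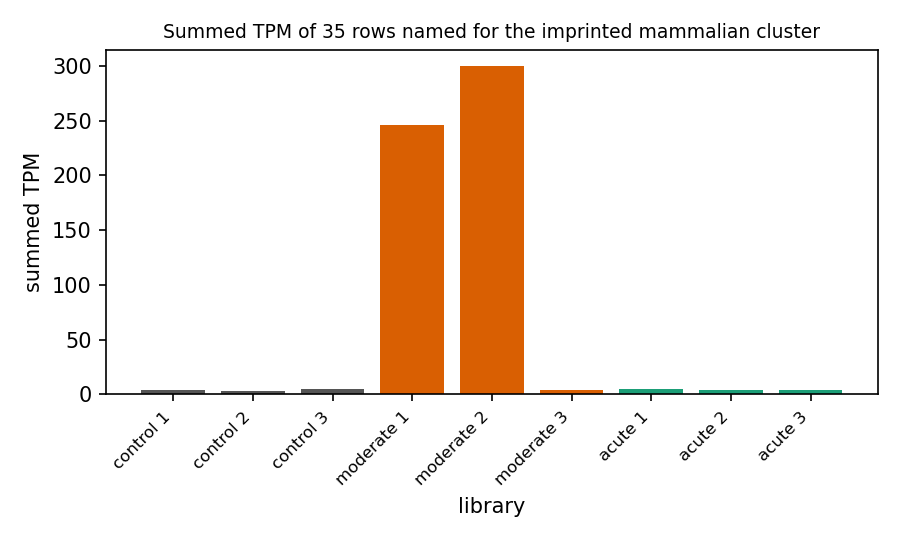
Summed abundance (TPM) of the 35 entries named for the imprinted miRNA cluster of placental mammals, 1 bar per library. Moderate hypoxia libraries 1 and 2 reach 246 and 300 TPM, and the other 7 libraries lie between 3.02 and 5.32 TPM.

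The comparison of moderate hypoxia with control asks which liver miRNAs respond to a moderate lack of oxygen. Abundance of miR-215-z, of the miR-192/215 family of liver and gut, rose by a log2 change of 2.13 (SE 0.242, adjusted p = 0.000322), from 186 ± 38.8 to 808 ± 14.4 TPM (SD, n = 3). Its relative miR-215-x rose by 1.13 (SE 0.183, adjusted p = 0.00243), and miR-10-x, encoded among the Hox genes, rose by 1.61 (SE 0.187, adjusted p = 0.000323). The fish miRNA miR-459-x fell, with a log2 change of -2.18 (SE 0.230, adjusted p = 0.000320), from 447 ± 93.9 to 96.7 ± 2.44 TPM. The hypoxia miRNA of mammals, miR-210, which hypoxia-inducible factor switches on in mammalian cells, had 3 measured forms, of which miR-210-y fell with a log2 change of -1.94 (SE 0.270, adjusted p = 0.00139). Its partner miR-210-z fell with a change of -1.49 (adjusted p = 0.00139), while miR-210-x had a value of 0.30 (adjusted p = 0.384) and did not pass (0.49 without control 3). By the naming rule the 18 nt entries miR-4454-z and miR-1386-z were also among the largest falls and miR-8159-x among the largest rises. With 1 library left out their log2 changes ranged from -2.32 to -1.38, -2.07 to -1.54 and 1.02 to 1.94. The call of miR-4454-z was lost under quantile normalization, and that of miR-8159-x held in 4 of 9 such fits.

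The miRNAs of red blood cells moved in both directions. Both miR-451-x and miR-144-y, made from a shared transcript in erythroid cells, fell, with log2 changes of -1.71 (SE 0.191, adjusted p = 0.000322) and -2.25 (SE 0.387, adjusted p = 0.00352). In contrast miR-486-x, also abundant in mammalian red blood cells, was 276-fold higher (95% counting interval 94.1 to 1338), with 1184 reads in the 3 moderate hypoxia libraries and 3 reads in the 3 controls (limma adjusted p = 5.83e-06). It read 41.7, 15.9 and 29.2 TPM in the moderate hypoxia libraries, so it was also present in library 3. Of the 6 red blood cell miRNAs tested, 4 fell and 1 rose, the same numbers adjusted over the list alone, 3 of these 5 passed under each scaling tried and each leave-out, and the list as a whole did not pass (adjusted p = 0.340). No reads of miR-1582-z were seen in the 3 moderate hypoxia libraries against 1168 in control, at least 558-fold lower with 3 reads over the group as the floor, or 341-fold without moderate hypoxia library 3 (limma adjusted p = 0.00243). Such intervals and floors cover counting error only.

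**Figure D2:**
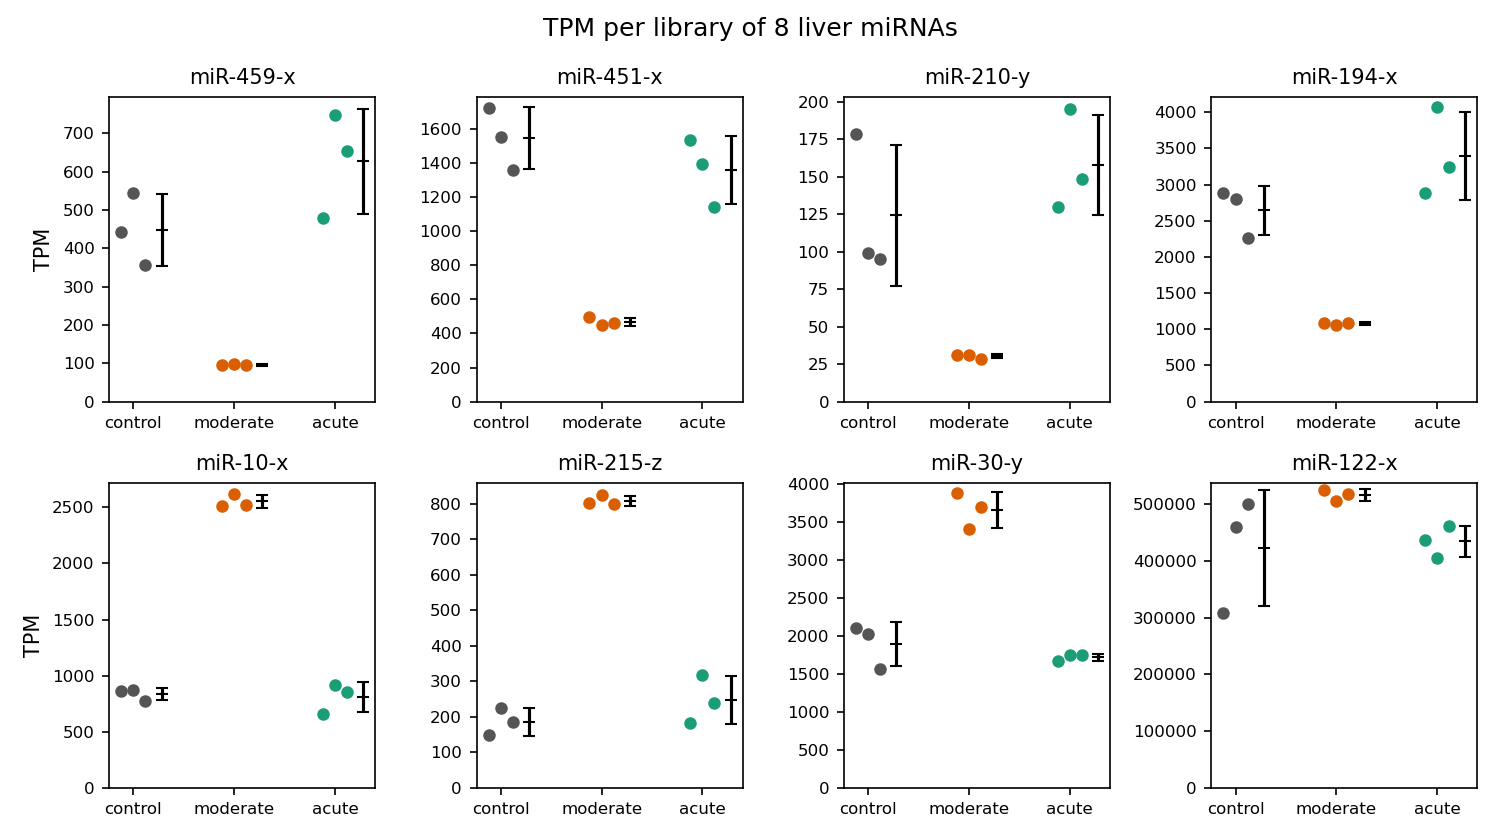
Abundance (TPM) of 8 miRNAs in each library, with 1 point per library and the mean with its SD for control, moderate hypoxia and acute hypoxia (n = 3 each). Under moderate hypoxia miR-459-x, miR-451-x, miR-210-y and miR-194-x are lower and miR-10-x, miR-215-z and miR-30-y are higher by group mean than in both other groups, and miR-122-x spans 307409 to 500523 TPM in the control libraries.

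Of 34 measured miRNAs known to respond to hypoxia in mammals, 11 fell under moderate hypoxia (11 adjusted over the list alone), none rose, and 23 did not pass. The list did not pass as a group (adjusted p = 0.0622, or adjusted p = 0.643 with an estimated correlation). It did pass, as lower, with a pseudocount of 5 (adjusted p = 0.0192), without a filter (adjusted p = 6.76e-05) and without control 2 (adjusted p = 0.0476), moderate hypoxia 2 (adjusted p = 0.0190) or acute hypoxia 1 (adjusted p = 0.0497). Without a filter the miR-17-92, miR-29, teleost-specific and red blood cell lists described below also passed as lower (adjusted p = 0.00564, 0.0383, 0.0383 and 0.0383), but over the tested miRNAs with an estimated correlation had adjusted p of 0.643, 0.643, 0.643 and 0.661. Of the 11, only miR-210-y and miR-210-z passed under each of 4 other scalings and without each library in turn. The abundant miR-26-x fell with a log2 change of -1.14 (adjusted p = 0.0236) and passed under none of those scalings. In the miR-17-92 clusters, which drive cell proliferation, 7 of 17 members fell (9 adjusted over the list alone; list adjusted p = 0.180), led by miR-106-z with -1.89 (adjusted p = 0.00456) and miR-17-x with -1.84 (adjusted p = 0.00406), and 3 of the 7 passed under each scaling and each leave-out. Of 21 miRNAs tied to glucose and lipid metabolism, 8 fell and 1 rose (11 and 2 adjusted over the list alone; list adjusted p = 0.315). Of these 9 only miR-144-y passed under each of the 4 scalings and without each library. The call of miR-33-y, encoded within the genes of the sterol regulators SREBP, had a log2 change of -1.92 (adjusted p = 0.0463) and was lost under all 4 scalings. Control 1 read 87.2 TPM of miR-33-y against 12.1 and 17.4 in the other controls, and without it the log2 value was -1.09 (adjusted p = 0.120).

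Among liver-enriched miRNAs 2 of 16 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.278). The fall was that of miR-194-x, which shares transcripts with miR-192 and miR-215, with a log2 change of -1.28 (SE 0.195, adjusted p = 0.00174), from 2647 ± 338 to 1081 ± 19.3 TPM. The rises were miR-22-y with 0.88 (adjusted p = 0.0166) and miR-192-x with 0.61 (adjusted p = 0.0445). The call of miR-22-y was lost without moderate hypoxia library 1 (adjusted p = 0.0614) or library 2 (adjusted p = 0.0519), and that of miR-192-x held in 2 of 9 such fits, those without control 1 or acute hypoxia 1. The dominant miR-122-x had a value of 0.32 (adjusted p = 0.254) and miR-122-y of 1.41 (adjusted p = 0.124), and neither passed. Without control 1, which read 175 TPM of miR-122-y against 1357 and 737, these values were 0.11 and 0.58, and without control 2 miR-122-y passed with 2.05 (adjusted p = 0.0462). The liver-enriched list passed as higher among miRNAs of at least 10 TPM (adjusted p = 0.0455), but had an adjusted p of 0.661 over all tested miRNAs with an estimated correlation. In the miR-30 family 1 of 3 members rose (1 adjusted over the list alone; list adjusted p = 0.340): miR-30-y, with a log2 change of 0.96 (SE 0.182, adjusted p = 0.00531).

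In the teleost pair miR-462 and miR-731, which hypoxia-inducible factor raises in zebrafish, 1 of 5 members fell (1 adjusted over the list alone; list adjusted p = 0.660). This was miR-731-y, with -1.66 (adjusted p = 0.00484), a call lost under quantile normalization. The others read -0.14 for miR-462-x, -0.45 for miR-462-y, 0.016 for miR-462-z and -0.17 for miR-731-x, and miR-462-x and miR-731-x turned positive under each of 4 other scalings and read -0.43 and -0.47 without control 1. Of 18 teleost-specific miRNAs 6 fell, miR-459-x and miR-722-y (-0.90) among them, and 1 rose (6 and 1 adjusted over the list alone; list adjusted p = 0.278). Of these 7 calls 2 passed under each scaling, and that of miR-722-y was lost under 3 of the 4. The group of miR-10, miR-99, miR-100 and miR-125, near Hox and let-7 genes, held 2 rises and 3 falls in 12 (2 and 3 adjusted over the list alone; list adjusted p = 0.996). Within it miR-10-x rose while miR-99-z fell with -1.41 (adjusted p = 0.00484), and both passed under every one of these scalings and leave-outs. In the cluster of miR-183, miR-96 and miR-182 miR-182-x rose with 1.42 (adjusted p = 0.00692) from 0.778 ± 0.348 TPM, miR-96-x fell with -0.77 (lost under all 4 scalings), and the list of 3 did not pass (adjusted p = 0.606; 1 and 1 adjusted over the list alone).

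Of the endothelial miR-126, 1 of 2 members fell (2 adjusted over the list alone): miR-126-y, with -0.98 (SE 0.200, adjusted p = 0.00676). Among leukocyte miRNAs 2 of 8 fell (2 adjusted over the list alone; list adjusted p = 0.820), miR-146-x with -0.70 and miR-223-y with -0.83, and both calls were lost under all 4 scalings. Of 14 miRNAs of oxidative stress and inflammation 4 fell (6 lower and 2 higher adjusted over the list alone; list adjusted p = 0.606), and only miR-144-y passed under each scaling and each leave-out. In stroma and smooth muscle 2 of 10 fell, miR-214-x and miR-214-y, and 1 rose, miR-143-x with 0.91 (2 and 1 adjusted over the list alone; list adjusted p = 0.891). In epithelium 2 of 9 fell, miR-429-y with -0.97 and miR-205-x with -1.06 (1 adjusted over the list alone; list adjusted p = 0.996). In the miR-29 family 1 of 3 fell, miR-29-x with -0.75 (3 adjusted over the list alone; list adjusted p = 0.286), and in the let-7 family 1 of 4 rose, let-7-y with 0.83 (1 adjusted over the list alone; list adjusted p = 0.278). None of the calls in the last 4 lists passed under every scaling and every leave-out.

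In striated muscle 1 of 6 miRNAs fell, miR-206-y with -1.26 (1 lower and 1 higher adjusted over the list alone; list adjusted p = 0.660), a call lost without moderate hypoxia library 1 (adjusted p = 0.106) or library 2 (adjusted p = 0.0618). No member passed among 3 of the miR-181 family (list adjusted p = 0.486), 6 of the miR-15/16 family (0.876), 7 of nervous tissue (0.278), 5 of pancreas (0.278), 2 of the miR-34 family and 1 of gonad and early embryo. Adjusted over the list alone, 1 member of the miR-34 family was higher, miR-34-x, with 5.30, 5.31 and 0.363 TPM in the moderate hypoxia libraries, 1 of the 58 entries high in libraries 1 and 2. Of 211 predicted miRNAs tested 4 rose and 25 fell (4 and 20 adjusted over the list alone; list adjusted p = 0.820), and 7 of these 29 passed under each scaling and each leave-out. Entries of the same sequence count separately here, and the 7 hold 2 sequences that are each listed under 2 names. A predicted sequence listed under 2 names, TCCCGGGTTTCGGCACCA, fell with -1.77 (adjusted p = 0.00406). The test compares a list with all other miRNAs, and its direction differed in sign from the median and mean of the miR-15/16 family (-0.11 and -0.096) and of stroma (-0.30 and -0.11). For striated muscle it was up, with a median of 0.071 and a mean of -0.11.

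In total 123 of 481 miRNAs passed the limma test (38 higher, 85 lower), and 83 of them changed at least 2-fold (30 higher, 53 lower). Counted once per distinct sequence, 110 of 399 passed. The authors' own table of this comparison, from a test that is not named, has 113 entries higher and 38 lower at a false discovery rate under 0.05 over all 1413 entries. Of the 113, 55 are among the 58 entries high in libraries 1 and 2, and over the 481 tested miRNAs it has 54 higher and 31 lower. It shares 69 calls with the limma test, 0 of them with the opposite sign. The groups did not overlap for 208 miRNAs, or 43.2%. Chance gives 10% if all libraries are independent, and more if library 3 depends on libraries 1 and 2. The split into rises and falls moves with the scaling: the median change of all tested miRNAs was -0.22 in deposited units, and 58 were higher and 43 lower with trimmed mean of M values scaling (median 0.061), 54 and 48 with median of ratios (0.0065), 40 and 40 with quantile normalization (-0.034), and 56 and 55 without miR-122-x (0.0061). None of the 123 changed sign under these 4 scalings, which shared 81, 86, 70 and 90 of the calls. All 85 falls lay below and all 38 rises above the median change. For the rises this was fixed, since the median was below 0, and the falls were called for being low. Of the 38 rises 16 were among the 58 entries more than 4 times higher in moderate hypoxia libraries 1 and 2 than in library 3. Library 3 lay above every control for 12 of these 16, for 22 of the other 22 rises and below every control for 85 of 85 falls, in calls that it helped to make. In the fit without library 3, 22 of 41 rises were among the 58 entries. Library 3 lay above every control for 17 of the other 19 and below every control for 57 of 57 falls. This is no independent check. At abundant miRNAs library 3 lay near the mean of libraries 1 and 2, and the same controls made the calls. Without the 58 entries high in libraries 1 and 2, 114 miRNAs passed, without both libraries 9 passed, with 1 library left in the group that is assumed to vary like the other groups, and without library 3 it was 98. Leaving out control 1 gave 81 calls, moderate hypoxia 1 gave 63 and moderate hypoxia 2 gave 60. The rise of miR-127-y (4.12 (adjusted p = 0.0296)) came from libraries 1 and 2 and held in 3 of 9 fits that leave out 1 library, with 174, 213 and 2.36 TPM.

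The comparison of acute hypoxia with control asks which liver miRNAs respond to an acute lack of oxygen over 12 h. No single miRNA passed the limma test: 0 of 481 had an adjusted p under the threshold, 47 had an unadjusted p under 0.05 (34 higher, 13 lower), and voom on the recovered reads gave 0 and 40. The lowest unadjusted p belonged to the predicted CGTCTCCCTGTGCTGGGCTTGG, with a log2 value of 1.03 (SE 0.263, adjusted p = 0.331), and next stood TGTCACCACAAAAGTAAACTCT with -0.85 and TCCCGGGTTTCGGCACCA with 1.16. Of known names miR-216-x, a pancreatic miRNA, read 1.37 and miR-1260-z 1.27, both with an adjusted p of 0.331. The hypoxia miRNA miR-210 read 0.21 (x), 0.38 (y) and 0.40 (z), with adjusted p of 0.818, 0.645 and 0.557. The fish pair read -0.14 for miR-462-x, -0.19 for miR-462-y, -0.15 for miR-462-z, -0.31 for miR-731-x and -0.86 for miR-731-y, and miR-122-x read 0.069 and miR-122-y 1.49. Some of these moved by over 1.5 times with 1 library left out. Without control 1 miR-122-x read -0.14, miR-122-y 0.65, miR-210-x 0.12, miR-210-y 0.67, miR-462-x -0.43, miR-731-x -0.60 and miR-731-y -0.52. Without acute hypoxia 2 miR-210-x and miR-210-y read 0.043 and 0.22.

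As groups, 2 of 22 lists were lower under acute hypoxia, with no member past the test alone. These were the 12 miRNAs of the group of miR-10, miR-99, miR-100 and miR-125 (median log2 -0.28, adjusted p = 0.00883) and the 6 of striated muscle (median -0.26, adjusted p = 0.0411). With an estimated correlation both calls were lost (adjusted p = 0.790 and adjusted p = 0.790). Members of the first read -0.80 for miR-100-x, -0.059 for miR-125-x and -0.42 for miR-99-x, and of the second -0.057 for miR-499-x, -0.29 for miR-1-z and -0.57 for miR-133-z. Without control 1, which read 120350 TPM of miR-100-x against 36452 and 55286, the values were -0.32 for miR-100-x, -0.043 for miR-99-x, -0.079 for miR-1-z and 0.065 for miR-499-x. Over all fits that leave out 1 library miR-100-x ranged from -1.18 to -0.32 and miR-99-x from -0.64 to -0.043. Without control 1 neither list passed, and the striated muscle call was also lost without control 2, control 3, moderate hypoxia 2, acute hypoxia 1 or acute hypoxia 3. It was lost as well with a pseudocount of 5, trimmed mean of M values or median of ratios scaling, the replicate block, without moderate hypoxia 1 and 2 together and among miRNAs of at least 10 TPM, where the other list was lost too. The teleost pair miR-462 and miR-731 had an adjusted p of 0.0875 and passed without control 1 (adjusted p = 0.00128) and without a filter (adjusted p = 0.0148), but had an adjusted p of 0.790 with an estimated correlation. The teleost-specific list passed as lower without a filter (adjusted p = 0.0148) or without acute hypoxia 2 (adjusted p = 0.0301), and the liver-enriched list as higher without a filter (adjusted p = 0.0408), but both had an adjusted p of 0.790 with an estimated correlation, which was run only on the tested 481 miRNAs and all 9 libraries. The other 19 lists had adjusted p from 0.242 to 0.708, none with a member past the test over all miRNAs, and 1 pancreatic miRNA was higher adjusted over the list alone. The test pointed down while the median was above 0 for the hypoxia-responsive (0.077), let-7 (0.014), miR-17-92 (0.015), oxidative stress (0.039) and nervous tissue (0.14) lists. The miR-29 (0.0062) and leukocyte (0.025) lists had a mean above 0 with a median below it. The groups did not overlap for 54 of 481 miRNAs, or 11.2%, where chance gives 10%. In simulated data with 200 of 481 miRNAs changed, 80.6% of 2-fold and 95.5% of 4-fold changes were found. With fewer changed miRNAs or a wider spread fewer would be found, so these shares do not say what was missed here.

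The comparison of acute with moderate hypoxia asks how the responses to the 2 degrees differ. Rises and falls here are differences from the moderate hypoxia libraries, which themselves differed from control, and are not changes against control. Against control 0 of 481 miRNAs passed under acute hypoxia. Higher under acute than under moderate hypoxia was miR-459-x, with a log2 change of 2.66 (SE 0.230, adjusted p = 4.30e-05), at 626 ± 136 TPM. The erythroid miR-144-y and miR-451-x were also higher, with 2.55 (SE 0.387, adjusted p = 0.00113) and 1.52 (adjusted p = 0.000338). The hypoxia miRNAs miR-210-y and miR-210-z were higher with 2.32 (SE 0.270, adjusted p = 0.000201) and 1.89 (adjusted p = 0.000167), while miR-210-x read -0.084 (adjusted p = 0.800). Lower under acute hypoxia were miR-215-z with -1.74 (SE 0.242, adjusted p = 0.000620), miR-10-x with -1.67 (adjusted p = 0.000167), miR-30-y with -1.09 (adjusted p = 0.00203) and miR-215-x with -0.85 (adjusted p = 0.00722). With 2 reads against 1184, miR-486-x was 405-fold lower (95% counting interval 112 to 3346), and with 1995 reads against none miR-1582-z was at least 973-fold higher. It read 34.7, 25.2 and 156 TPM in the acute hypoxia libraries, and without acute hypoxia 3 the bound was 436-fold. The predicted TCCCGGGTTTCGGCACCA rose with 2.93 (adjusted p = 0.000167).

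Of 34 mammalian hypoxia-responsive miRNAs 13 were higher under acute hypoxia (15 adjusted over the list alone; list adjusted p = 0.223, or adjusted p = 0.00131 without a filter and adjusted p = 0.717 with an estimated correlation), and 4 of the 13 passed under each scaling and each leave-out. In the miR-17-92 clusters 7 of 17 were higher (7 adjusted over the list alone; list adjusted p = 0.263), with miR-106-z at 2.03, miR-17-x at 1.95 and miR-19-z at 1.62, and 5 of the 7 passed throughout. Of the 21 metabolic miRNAs 10 were higher (12 adjusted over the list alone; list adjusted p = 0.263), but only miR-144-y passed throughout. Both endothelial members rose (2 adjusted over the list alone), miR-126-y with 1.22 (adjusted p = 0.00177) and miR-126-x with 1.04 (adjusted p = 0.00721). Among red blood cell miRNAs 3 of 6 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.691). In the liver-enriched list miR-194-x rose with 1.64 (adjusted p = 0.000221) and miR-192-x fell with -0.66, a call lost without any 1 of the 3 moderate hypoxia libraries or of acute hypoxia 2 and 3 (1 higher and 0 lower adjusted over the list alone; list adjusted p = 0.685). Of 211 predicted miRNAs 40 rose and 3 fell (27 and 1 adjusted over the list alone; list adjusted p = 0.574), and 12 of these 43 passed throughout.

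In the remaining lists the last value after each count is the list's adjusted p. Of 18 teleost-specific miRNAs 5 rose and 1 fell (5 and 1 adjusted over the list alone; 0.728), and of the miR-10, miR-99, miR-100 and miR-125 group 2 rose and 3 fell (2 and 3 adjusted over the list alone; 0.263). Among stroma and smooth muscle miRNAs 4 of 10 rose (4 adjusted over the list alone; 0.936), of which 0 passed under each scaling, and among those of oxidative stress 4 of 14 rose and 1 fell (5 and 1 adjusted over the list alone; 0.809). Under each scaling and each leave-out 2 of the 6 teleost-specific calls, 1 of the 5 of the miR-10 group and 1 of the 5 of oxidative stress passed. Of the miR-30 family miR-30-x rose with 0.96 (lost under trimmed mean and median of ratios scaling) and miR-30-y fell (1 and 1 adjusted over the list alone; 0.728), and of leukocyte miRNAs miR-223-y rose (lost under all 4 scalings) and miR-146-y fell (1 and 1 adjusted over the list alone; 0.941). Rises numbered 2 of 3 in the miR-29 family (3 adjusted over the list alone; 0.397) and 2 of 3 in the miR-181 family (3 adjusted over the list alone; 0.445), and all 4 of these calls were lost under all 4 scalings. Rises numbered 1 of 6 in the miR-15/16 family (0 adjusted over the list alone; 0.941) and 1 of 9 in epithelium (1 adjusted over the list alone; 0.728), and neither passed under each scaling. Single falls were miR-182-x with -1.63 (adjusted p = 0.00292) in its cluster (1 lower and 1 higher adjusted over the list alone; 0.263) and miR-1-z with -1.02 in striated muscle (1 adjusted over the list alone; 0.223). The call of miR-1-z was lost without moderate hypoxia 2 (adjusted p = 0.0565) or acute hypoxia 3 (adjusted p = 0.0507), and that of miR-146-y without moderate hypoxia 2 (adjusted p = 0.0513). In nervous tissue miR-9-z fell with -2.14 (0 adjusted over the list alone; 0.223), with 77.2, 67.1 and 5.87 TPM in the moderate hypoxia libraries, and of the fits that leave out 1 library it passed only without moderate hypoxia 3 (-3.28). No member of the teleost pair (0.807), let-7 (0.223), pancreas (0.574), miR-34 or gonad lists passed. The test pointed down while median and mean were above 0 for the teleost pair, liver-enriched, miR-30 and pancreas lists (medians 0.0014, 0.063, 0.35 and 0.046).

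In total 147 of 481 miRNAs passed the limma test (110 higher, 37 lower), 103 of them at least 2-fold (73 higher, 30 lower). Counted once per distinct sequence, 130 of 399 passed. The authors' own table has 70 entries higher and 95 lower over all entries, 52 of the 95 among those 58 entries, and 56 higher and 52 lower over the tested miRNAs. It shares 90 calls with the limma test, 0 of them with the opposite sign. The groups did not overlap for 254, or 52.8%, where chance gives 10% if all libraries are independent. The median change was 0.32 in deposited units, with 51 higher and 78 lower under trimmed mean of M values scaling (median -0.065), 54 and 69 under median of ratios (0.0095), 58 and 54 under quantile normalization (0.044), and 77 and 49 without miR-122-x (0.088). Of the calls only that of miR-181-y (0.52) changed sign under these scalings, to -0.092 with quantile normalization. Without the 58 entries high in moderate hypoxia libraries 1 and 2 the count was 136, and without both libraries 28. Leaving out moderate hypoxia 1 gave 97 calls, moderate hypoxia 2 gave 72, acute hypoxia 2 gave 75 and acute hypoxia 3 gave 77.

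**Figure D3:**
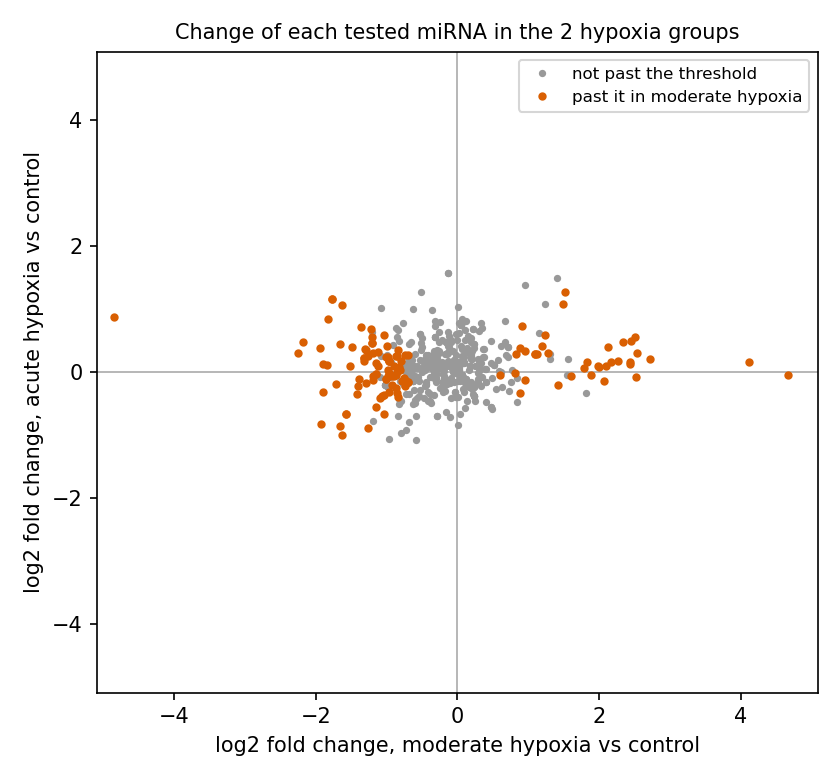
Log2 change against control under moderate hypoxia (x axis) and under acute hypoxia (y axis), 1 point per tested miRNA (481), with those that passed the test under moderate hypoxia coloured. The points spread widely along the x axis and narrowly along the y axis, with a correlation of 0.11 across miRNAs.

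Across the 481 miRNAs, which are not independent replicates, the changes against control in the 2 hypoxia groups had a Pearson correlation of 0.11. It ranged from 0.021 to 0.24 with 1 library left out. The Spearman correlation was 0.13 and the covariance 0.0399. Both changes use the same control libraries. Over 100 draws, unchanged simulated groups set against shared controls gave a mean correlation of 0.45 (-0.45 to 0.88). Their mean covariance was 0.0586 (-0.0225 to 0.150). The sign was shared by 52.2% of miRNAs, against 65.3% (29.3 to 85.6%) in the simulation. The observed Pearson correlation, covariance and shared sign all lay inside the simulated ranges. No miRNA passed in both comparisons, with 0 from simulated shared controls and 0 from independent lists, since none passed under acute hypoxia by limma, with 47 at an unadjusted p under 0.05. The difference between miRNAs that passed in one group and not the other is tested in the comparison of acute with moderate hypoxia.

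The 10 most abundant miRNAs of each library took 81.5 ± 2.98% of its abundance in control, 84.9 ± 0.121% under moderate and 82.0 ± 0.503% under acute hypoxia (SD, n = 3). With 1 library left out, the share of the top 10 under moderate hypoxia was 1.64 to 4.37 percentage points above control. Predicted miRNAs took 0.227 ± 0.0351%, 0.137 ± 0.00613% and 0.218 ± 0.00945%. Entries with reads numbered 1052 ± 37.8, 1142 ± 26.6 and 1082 ± 10.97, but moderate hypoxia libraries 2 and 3 were the deepest of the 9, and libraries 1 and 2 hold the 58 entries described above. At 1 TPM or more the numbers were 453 ± 22.0, 467 ± 27.2 and 484 ± 4.62, so acute hypoxia was then above moderate hypoxia (exact p = 0.6). Exact two-sided permutation tests gave p = 0.1 for the shares and for entries with reads in moderate hypoxia against control and in acute against moderate hypoxia, which is the smallest p that 3 libraries against 3 allow. In acute hypoxia against control they gave exact p = 1, 0.8 and 0.2.

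The predicted miRNA in the title of the series is named there together with the lncRNA LOC110519952 and the glucose transporter transcript glut1a. In the deposited values of acute hypoxia and control that name belongs to the sequence GAGTAAATGGAAAGGTCTGA (20 nt). The match is by name alone, and of 347 predicted names shared by both naming runs 7 carry the same sequence. The sequence is listed only in the deposited table of acute hypoxia and control, so its level under moderate hypoxia is not analysed here. It read 38.9, 5.65 and 9.48 TPM in the control libraries and 9.54, 5.21 and 5.58 TPM under acute hypoxia, means of 17.99 ± 18.2 and 6.78 ± 2.40 TPM (SD, n = 3). In limma the log2 value was -0.90 (SE 0.513, adjusted p = 0.653) and did not pass, and an exact permutation test of the TPM gave p = 0.3. The log2 value was -0.14 without control 1 and -1.44 without control 2. The authors' own table lists a log2 change of -1.41 with p = 0.0132 and a false discovery rate of 0.658 from a test that is not named, which across all entries of that table left 0 past 0.05.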

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

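Chosen after the data were seen were 1 entry per distinct set of values, voom, the second table and the GC trend. So were the removals of libraries 1 and 2 or of the 58 entries. The other tests of this part were fixed before. Fixed beforehand too, the quasi-likelihood and negative binomial tests on recovered reads were not run. The count of 123 for moderate hypoxia against control stayed between 82 and 142 under the alternatives not named next. It was 75 with a mean of at least 10 TPM, where fewer miRNAs were tested, 80 with quantile normalization, where the cause was not tested, and 9 without moderate hypoxia libraries 1 and 2, where fewer libraries remain; leaving out 1 library gave 60 to 129. For acute hypoxia against control the count was 0 in every adjusted fit, the second table and voom included, and 16 at an unadjusted p with a 2-fold change. For acute against moderate hypoxia it was 83 with at least 10 TPM and 28 without libraries 1 and 2, 72 to 183 with 1 library left out, and between 103 and 183 otherwise. Lists past the test in moderate hypoxia against control numbered 1 with a pseudocount of 5 (hypoxia-responsive), 5 without a filter, 1 with at least 10 TPM (liver-enriched) and 0 to 1 with 1 library left out (hypoxia-responsive). In acute hypoxia against control they numbered 1 with a pseudocount of 5, with trimmed mean of M values scaling, with median of ratios scaling, with the replicate block and without libraries 1 and 2, where the striated muscle list was lost each time, 5 without a filter, 0 with at least 10 TPM and with an estimated correlation, and 1 to 3 with 1 library left out. In acute against moderate hypoxia the hypoxia-responsive list passed without a filter. The cause of these list changes was not tested. Between acute hypoxia and control, the share of the most abundant miRNAs differed by -0.112 for the top 50 and by -1.24 to 1.49 for the top 10 with 1 library left out, and that of predicted miRNAs by -0.0247 to 0.0103. The number of entries with reads was lower under acute than under moderate hypoxia, and with a minimum of 1 TPM the direction reversed, to 16.3 more under acute hypoxia; depth and the 58 entries were not tested as the cause. Of the 107 named calls 82 were lost under some alternative and 2 changed sign, and of 63 named values that did not pass 21 changed sign and 6 passed somewhere. The values that changed sign are log2 changes, and the cause was not tested. With trimmed mean of M values scaling these were miR-462-x 0.22, miR-731-x 0.19, miR-199-x 0.061 in moderate hypoxia against control, and miR-122-x -0.055 in acute hypoxia against control, and miR-122-y -0.41, miR-462-x -0.48, miR-462-y -0.010 in acute hypoxia against moderate hypoxia. With median of ratios scaling these were miR-462-x 0.16, miR-731-x 0.13, miR-199-x 0.0012 in moderate hypoxia against control, and miR-122-x -0.036 in acute hypoxia against control, and miR-122-y -0.34, miR-462-x -0.41 in acute hypoxia against moderate hypoxia. With quantile normalization these were miR-462-x 0.023, miR-731-x 0.24, miR-181-x 0.11 in moderate hypoxia against control, and miR-125-x 0.093 in acute hypoxia against control, and miR-462-x -0.13, miR-181-y -0.092 in acute hypoxia against moderate hypoxia. Without miR-122-x these were miR-462-x 0.094, miR-731-x 0.066 in moderate hypoxia against control, and miR-122-y -0.15, miR-462-x -0.22 in acute hypoxia against moderate hypoxia. With a pseudocount of 5 these were miR-462-z -0.0023 in moderate hypoxia against control. Without moderate hypoxia libraries 1 and 2 these were miR-462-z -0.059 in moderate hypoxia against control, and miR-462-x -0.016, miR-462-y -0.00048, miR-9-z 0.13 in acute hypoxia against moderate hypoxia. With the trend on GC content and length removed these were miR-462-z -0.27 in moderate hypoxia against control, and miR-122-x -0.0079, miR-462-z 0.090 in acute hypoxia against control, and miR-122-y -0.15, miR-462-y -0.036, miR-462-z 0.36, miR-731-x 0.13 in acute hypoxia against moderate hypoxia. With voom these were miR-101-y -0.0013 in moderate hypoxia against control. With 1 library left out some values crossed 0. In moderate hypoxia against control the ranges were miR-462-x -0.43 to 0.018, miR-462-z -0.19 to 0.22, miR-101-y -0.39 to 0.25. In acute hypoxia against control the ranges were miR-122-x -0.14 to 0.21, miR-462-x -0.43 to 0.020, miR-462-y -0.31 to 0.017, miR-462-z -0.36 to 0.053, miR-192-x -0.19 to 0.11, miR-125-x -0.25 to 0.084, miR-499-x -0.29 to 0.24, miR-499-y -0.38 to 0.15. In acute hypoxia against moderate hypoxia the ranges were miR-122-y -0.24 to 0.61, miR-210-x -0.25 to 0.013, miR-462-x -0.034 to 0.041, miR-100-x -0.47 to 0.20. Other log2 changes moved by over 1.5 times with 1 library left out without crossing 0: miR-33-y -2.46 to -1.09, miR-122-x 0.11 to 0.46, miR-122-y 0.58 to 2.05, miR-210-x 0.20 to 0.49, miR-731-x -0.47 to -0.0081, miR-199-x -0.45 to -0.17, miR-100-x -1.07 to -0.21, let-7-x 0.022 to 0.14, miR-23-y -1.22 to -0.54, miR-99-x -1.32 to -0.72 in moderate hypoxia against control; miR-122-y 0.65 to 2.12, miR-210-x 0.043 to 0.40, miR-210-y 0.22 to 0.67, miR-731-x -0.60 to -0.14, miR-731-y -1.11 to -0.52, miR-199-x 0.14 to 0.43, miR-100-x -1.18 to -0.32, miR-30-x 0.25 to 0.62, miR-22-y 0.22 to 0.57, miR-26-x -0.92 to -0.29, miR-181-x 0.055 to 0.32, miR-101-y 0.12 to 0.80, miR-100-z -1.46 to -0.40, miR-99-x -0.64 to -0.043, miR-1-z -0.46 to -0.079 in acute hypoxia against control; miR-462-y 0.14 to 0.46, miR-462-z -0.33 to -0.060, miR-731-x -0.26 to -0.044, miR-26-x 0.22 to 0.85, miR-101-y 0.24 to 0.80, miR-9-z -3.28 to -1.53 in acute hypoxia against moderate hypoxia. Depth limits what low entries show: 3 reads correspond to 0.182 to 0.355 TPM.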

Other observations

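All tests in this part were chosen after the result was seen, apart from the counts over other splits of the libraries, whose design was fixed before the data were examined but whose prediction was written afterwards.

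Of 14 tested sequences of 18 nt, 13 end in CCA, the bases found at the 3' end of mature tRNAs, so this ending cannot be told apart from the short length. The set was picked after some of its members, miR-1386-z and miR-7977-z among them, were seen among the largest rises of acute against moderate hypoxia. In that comparison 12 of the 13 were higher (median log2 change 1.77), a count that selection raises. Against control 6 of the 13 were lower under moderate hypoxia (median -1.20), and 0 passed under acute hypoxia (median 0.81). They summed to 708, 757 and 785 TPM in control, 619, 275 and 462 TPM under moderate hypoxia and 962, 1309 and 1773 TPM under acute hypoxia, over 2-fold apart within the moderate hypoxia group. Whether these reads are miRNAs or tRNA fragments was not tested.

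The 3 moderate hypoxia libraries lay apart from the other 6 on the first principal component, library 3 (7.83) about midway between libraries 1 and 2 (15.3 and 17.1) and the nearest control (-3.23). A trend on GC content and length as the whole cause is argued against, since 116 of the 123 calls stayed past the threshold once it was removed. Whether reads of another organism caused the falls stays open. If they diluted every trout miRNA alike, the 10 most abundant would fall like the rest. Their median log2 change was -0.15, against -1.14 for the called falls. These falls were picked for being low, and foreign reads could also count toward miRNAs that a mammal shares with trout. The values therefore cannot decide it. For the rises this cause stays open too. Of the 38, 16 were among the entries more than 4 times higher in libraries 1 and 2 than in library 3, where the entries of the placental cluster sum to 3.94 TPM, within the range of the controls (3.02 to 4.52 TPM). Library 3 lay above every control for 34 of the 38, 12 of those 16 included, but it is 1 library and helped to make these calls. A separate preparation or run of the moderate hypoxia libraries may also be the cause and cannot be told apart from the treatment, since 0 labels give a batch, lane, run or date.

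Moderate hypoxia library 3 lay between libraries 1 and 2 at 87.2% of 94 abundant miRNAs, against at most 66.0% for any other library, and its median distance from their mean was 0.0221 on the log2 scale, against 0.145 to 0.467 elsewhere. In library 3 the entries of the placental cluster reached 1.38% of the mean of libraries 1 and 2. This argues against a mix of the reads of libraries 1 and 2. A mix of their RNA from before those entries came in would lack them too, so it cannot be decided here. Chance closeness of 3 libraries of 1 group cannot be told apart from another cause, because the values were chosen after they were seen and only 1 library shows them. No biological explanation was tested.

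The entries named for the imprinted cluster of placental mammals, which trout lack, were higher in moderate hypoxia libraries 1 and 2 than in each of the other 7 for 77.1% of 35 entries. A candidate explanation is reads of a placental mammal in those libraries, a hypothesis found and tested on the same data. A response shared by the 3 moderate hypoxia libraries is argued against, since library 3 lay above every control for 14.3% of these entries.

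Other splits of the 6 libraries of each comparison into 3 against 3 were fitted on those 6 libraries alone. For moderate hypoxia against control 1 of 10 splits gave as many calls as the real 82, with at most 0 in any other. For acute hypoxia against control 10 of 10 splits gave as many as the real 0, with at most 0 in any other. For acute against moderate hypoxia 1 of 10 gave as many as the real 175, with at most 0 in any other. In the fit of all 9 libraries the real splits gave 123, 0 and 147 calls and any other split at most 0. With 10 splits no share under 0.05 can be reached.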
